A study of Rattus norvegicus with 47 samples.

How the data were processed

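Gene expression was measured on single-colour Affymetrix rat arrays in 47 liver samples of male Wistar rats. Per the labels' protocols, the rats received 1 initiating dose of the nitrosamine N-nitrosomorpholine (250 mg/kg) at 4 weeks of age, recovered for 3 weeks, and then drank phenobarbital (50 mg/kg per day) for up to 17 months. Frozen tissue was extracted with TRIzol and the miRNeasy kit and 250 ng of RNA was labelled with the 3' IVT Express kit. Formalin-fixed, paraffin-embedded (FFPE) lesions were microdissected with a laser and their RNA was isolated with a kit for fixed tissue (RNeasy), per the labels' protocols, and their labelling kit is not given in the sources used here.

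The values deposited by the authors are log2 probe set summaries and were used as deposited. The method of background correction, summarization and normalization is not given in the sources used here. The table held 31042 probe sets and no missing values. Array medians lay between 5.49 and 5.59 in the 28 frozen arrays and between 5.58 and 5.68 in the 19 FFPE arrays. The interquartile range of an array was 3.21 to 3.53 in frozen and 2.56 to 3.28 in FFPE tissue, and the mean correlation of an array with the other arrays of its fixation was 0.965 to 0.979 and 0.886 to 0.939. Arrays give no counts of molecules, so the number of arrays limits the precision.

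Probe sets with a single gene symbol (20826) were kept, 436 with several symbols and 9780 with none were left out, and each of the resulting 14217 genes was represented by the probe set with the highest mean in a fixation. It differed between fixations for 1727 genes, among them Glul, Tbx3, Igf2 and Alb, and joint fits of both fixations used that of the frozen arrays. Cyp2b1, the classical phenobarbital target, shares its probe set with another gene and was not tested.

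Samples were grouped by their group label. Frozen groups were surrounding liver (n = 7, 5 animals), nodules (n = 5, 3 animals, called minitumours in the source names), adenomas (n = 6, 2 animals), carcinomas (n = 4, 3 animals) and carcinomas labelled as carrying a beta-catenin mutation (n = 4, 3 animals). FFPE groups were surrounding liver (n = 4, 4 animals), foci (n = 9, 3 animals) and adenomas (n = 5, 3 animals). The 3 arrays named C43 normal (2 frozen, 1 FFPE) have labels that also call them surrounding tissue under phenobarbital, and they entered no comparison. The animal was taken from the sample title and the labelled control set, because the source-animal field gives 4 different numbers for the 4 samples of animal 21. The group label of beta-catenin carcinoma replicate 1 names the mutation and its source name does not, and the source name of FFPE adenoma replicate 4 reads surrounding tissue. Each was kept under its group label and left out as an alternative.

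Each fixation was fitted apart with limma 3.58.1 in R 4.3.3, as a linear model with group and animal as fixed terms and moderated statistics with an intensity trend. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over 14217 genes, with 17 residual degrees of freedom in frozen and 12 in FFPE tissue. Errors beside log2 changes are standard errors of the fit. Of 1078 changes of named genes, 40, none of them called, had the opposite sign to the difference of the group means, 15 of these between FFPE adenomas and foci and 8 between adenomas and nodules. In 16 of 103 list calls the median of the plain differences was over 1.5 times smaller than the fitted one. The animal number pairs the samples because lesions and surrounding liver come from the same rats. In frozen tissue, deviations from the group means had a median r of 0.127 within animals (50 pairs, 28 above 0.1) and -0.025 between animals. In FFPE tissue the medians were 0.11 within animals (23 pairs, 15 above 0.1) and -0.0395 between animals.

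The labels give each frozen lesion a control set, and 2 animals have more than 1 set. Each frozen comparison was also fitted with the control set in place of the animal as a block, which compares lesions with surrounding liver of the same set. This is called the matched fit and has 15 residual degrees of freedom. The surrounding arrays of the control sets of the carcinomas (n = 3) differed from the other surrounding arrays (n = 4) in 875 genes by limma. These 2 kinds of control sets are called batches below, a grouping drawn from the names of the control sets, as the labels name no batch. FFPE samples have 1 control set per animal, so both fits are the same there.

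Fixed lists of genes were tested with camera in limma, with a preset correlation between genes of 0.01 and with an estimated one, adjusted over 220 tests of 22 lists in 10 comparisons. The lists (328 genes, 287 measured) were Wnt/beta-catenin targets and pericentral genes, periportal genes, phenobarbital (CAR/PXR) responsive genes, NRF2 targets, foci and oncofetal markers, proliferation, bile acid synthesis and transport, fatty acid synthesis, cholesterol synthesis, fatty acid oxidation, glycolysis, male-predominant liver genes, acute phase, inflammatory mediators, immediate early genes, and markers of hepatocytes, stellate cells and fibroblasts, macrophages, endothelium, cholangiocytes, lymphocytes and blood cells. Of the 220 tests, 103 passed with the preset correlation and 4 of these also with the estimated one. The 4 were the NRF2 targets in FFPE foci and in FFPE adenomas, the periportal genes in FFPE foci, and the macrophage markers between FFPE adenomas and foci. The last did not pass with an estimated correlation in 8 of 14 fits with 1 array left out (adjusted p up to 0.118), and the other 3 passed in all.

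Named genes were chosen by a fixed rule. It takes 18 measured key genes, the 8 largest rises and 8 largest falls per lesion against surrounding liver among called genes that moved the same way in every animal holding both tissues, the 6 largest per direction between lesion types, and the 4 members with the lowest adjusted p of each list. The groups, tests, lists, naming rule and alternatives were fixed before the data were examined, with exceptions. These are the list and fixation tests in the matched fit, the test between the batches and the comparisons with plain group means. Others are the fits and tests named below as chosen after the data or results were seen.

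The fits were tested on simulated data in which 67 genes changed 2-fold. The share of these recovered was 76.1% (adenomas against nodules) to 91% (adenomas against surrounding liver) in the 7 frozen comparisons, and 29.9% for foci, 28.4% for FFPE adenomas and 37.3% between FFPE adenomas and foci. Alternatives covered the block, normalization, median centring, array weights, low values, probe set choice, a 2-fold minimum, means per animal, doubtful samples, the C43 arrays, and each sample and each animal left out in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.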

Results

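Liver lesions from 7 male rats given an initiating nitrosamine and then phenobarbital were profiled on expression arrays to describe how foci, nodules, adenomas and carcinomas differ, with the surrounding liver as control. The frozen set held 7 arrays of surrounding liver, 5 of nodules, 6 of adenomas, 4 of carcinomas and 4 of carcinomas labelled with a beta-catenin mutation. The FFPE set held 4 arrays of surrounding liver, 9 of foci and 5 of adenomas taken by microdissection. Changes are log2 differences between groups ± standard error from limma, adjusted for animals as blocks, and can differ from differences of the plain group means. Values from the matched fit compare lesions with the surrounding arrays of the same labelled control set.

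FFPE foci were compared with surrounding liver to find what marks these lesions (n = 9 and 4, 3 animals with both). Gstp1, the placental glutathione transferase used to stain rat liver foci, rose by 4.44 ± 0.40 (21.7-fold, adjusted p = 2.5e-08) and lay between 13.67 and 13.89 in all 9 foci against 7.15 to 12.17 in the surrounding samples. Ggt1, the gamma-glutamyl transferase that is the other classical focus marker, rose by 2.43 ± 0.24 (adjusted p = 9.48e-08). The largest rise was that of Defb1, an antimicrobial peptide, by 4.87 ± 0.37, followed by the aldo-keto reductase Akr1b8 by 4.68 ± 0.34, Pcp4 by 4.65 ± 0.31, Mmd by 3.77 ± 0.29, the annexin Anxa2 by 3.15 ± 0.30 and Dnaaf1 by 3.14 ± 0.49. In all, 258 genes rose and 194 fell (171 and 91 at least 2-fold). Gstp1 and Ggt1 rose in 3 of 3 animals, and the others were chosen for this.

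NRF2 targets, the antioxidant and conjugation genes driven by that stress-response factor, rose in 14 of 17 measured members in foci (15 when adjusted over the list alone) with a median of 1.49 (adjusted p = 2.13e-43, and 0.00232 with an estimated correlation). Among them were Srxn1, which repairs oxidized peroxiredoxins (3.26 ± 0.25), the aflatoxin aldehyde reductase Akr7a3 (2.40 ± 0.15) and Gclc, the rate-limiting subunit of glutathione synthesis (1.89 ± 0.15). Of the foci and oncofetal markers, 4 of 17 rose (6 adjusted over the list alone), namely Gstp1, Ggt1, Akr1b8 and the transcription factor Sox4 (1.27 ± 0.24). Their median was 0.15 and their mean 0.98 (adjusted p = 3.67e-06, and 0.0819 with an estimated correlation). Afp, H19, Igf2 and Gpc3, fetal liver genes, had changes of -0.12, -0.31, 0.15 and 0.14 that did not pass (adjusted p = 0.834 to 0.93). Phenobarbital-responsive genes rose in 4 of 16 and fell in 1 (adjusted p = 0.0389, and 0.366 with an estimated correlation). The rises included Ephx1 (0.84 ± 0.09) and Aldh1a1 (0.91 ± 0.14), and the fall was that of Cyp2c7 (-0.72 ± 0.13).

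Genes of both ends of the liver lobule fell in foci. Of the periportal genes, 7 of 16 fell (10 adjusted over the list alone; median -0.69, adjusted p = 4.74e-11, and 0.0123 with an estimated correlation). They included the serine dehydratase Sds (-2.23 ± 0.48) and Pck1, which controls gluconeogenesis (-1.58 ± 0.29). Wnt/beta-catenin targets and pericentral genes fell in 5 of 16 (6 adjusted over the list alone; median -0.56, adjusted p = 5.15e-07, and 0.125 with an estimated correlation). Cyp1a2 fell by 2.31 ± 0.44, Slc1a2 by 2.26 ± 0.40 and Cyp2e1, which oxidizes ethanol, by 1.03 ± 0.23. Other large falls were those of Cdh17 (-2.57 ± 0.47), Dhrs7l1 (-2.51 ± 0.62), Car3 (-2.38 ± 0.39), Sult1c3 (-2.22 ± 0.39) and Avpr1a (-2.19 ± 0.45).

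Bile acid genes fell in 5 of 14 in foci (11 fell and 1 rose adjusted over the list alone; adjusted p = 2.92e-08, and 0.0733 with an estimated correlation). Among them were Cyp8b1, which makes cholic acid (-2.17 ± 0.40), and Slc27a5, which activates bile acids (-1.85 ± 0.32). Male-predominant liver genes fell in 5 of 9 (6 fell and 1 rose adjusted over the list alone; adjusted p = 2.41e-06, and 0.0619 with an estimated correlation). They included Cyp2c11, the main male cytochrome (adjusted p = 4.53e-06). Fatty acid oxidation genes fell in 4 of 14 (7 adjusted over the list alone; adjusted p = 1.5e-06, and 0.145 with an estimated correlation). Acute phase genes fell in 3 of 14 (7 adjusted over the list alone; adjusted p = 5.71e-06, and 0.107 with an estimated correlation). The cholesterol synthesis list was lower as a whole with 0 of 13 members called (4 adjusted over the list alone; adjusted p = 0.000218, and 0.269 with an estimated correlation). Of the proliferation genes, 1 of 24 rose, the replication clamp Pcna (1.17 ± 0.27), while Mki67 had 0.83 ± 0.37 (adjusted p = 0.299; list adjusted p = 0.00708, and 0.26 with an estimated correlation).

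Markers of other cell types moved with these groups in foci. Macrophage markers fell in 4 of 11 (7 adjusted over the list alone; median -0.64, adjusted p = 3.83e-07, and 0.0733 with an estimated correlation). Stellate cell and fibroblast markers rose in 3 of 15, the collagens Col1a1 (1.21 ± 0.31), Col1a2 (1.12 ± 0.31) and Col3a1 (1.04 ± 0.22), without the list passing (adjusted p = 0.0534). Hepatocyte markers shifted down as a list with a median of -0.16 (adjusted p = 0.00354, and 0.269 with an estimated correlation), and 1 of 11, Apoa1, rose by 0.47 ± 0.11. Fatty acid synthesis (1 of 15 rose, the NADPH-producing enzyme Me1 by 1.28 ± 0.19), glycolysis, inflammatory mediators, immediate early genes and the endothelial, cholangiocyte, lymphocyte and blood cell markers did not pass (adjusted p = 0.0582 to 0.659). Fatty acid synthesis and glycolysis had medians below 0 and means above 0. Without surrounding replicate 1, 3 or 4, the count of called genes was 250, 248 or 245 in place of 452.

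**Figure D1:**
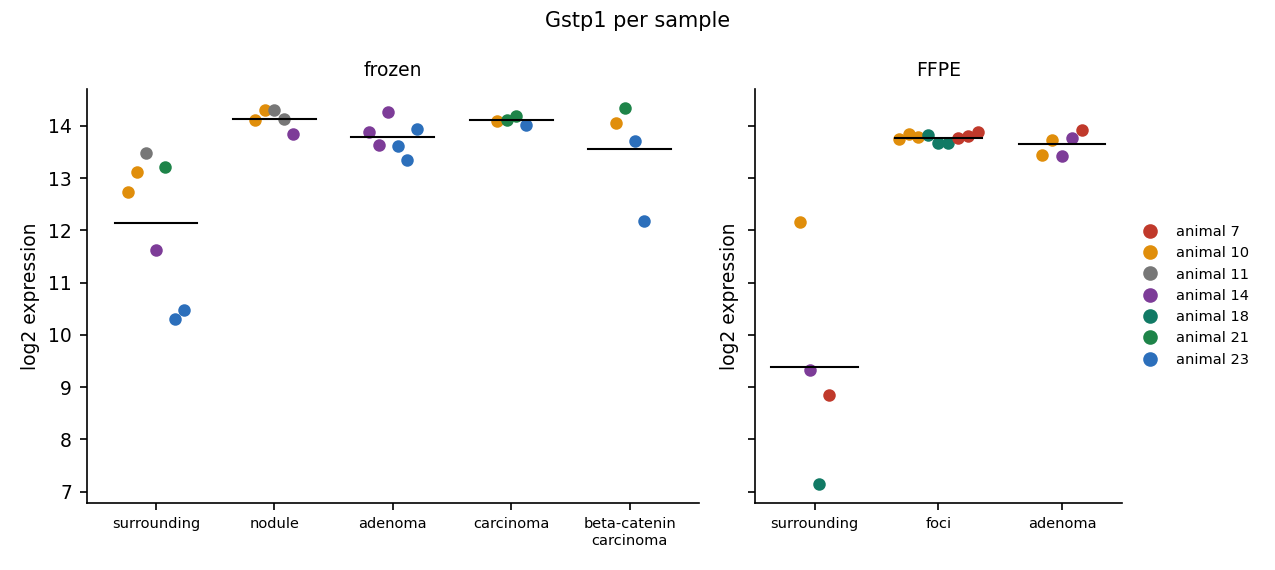
Log2 expression of Gstp1 per array (points, coloured by animal) with group means (lines) in frozen and FFPE tissue. The 9 foci lie between 13.67 and 13.89, and frozen surrounding liver spans 10.30 to 13.47.

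FFPE adenomas were compared with surrounding liver of the same fixation (n = 5 and 4, 3 animals with both). The same focus markers were far above surrounding liver, with Gstp1 at 4.03 ± 0.45 (adjusted p = 1.85e-06), Ggt1 at 2.09 ± 0.26, Pcp4 at 4.58 ± 0.35, Akr1b8 at 4.55 ± 0.38 and Defb1 at 4.40 ± 0.41. Dnaaf1 rose by 4.31 ± 0.55, Mmd by 3.51 ± 0.33, the aldehyde dehydrogenase Aldh3a1 by 3.37 ± 0.90 and Ugt2b7 by 3.23 ± 0.67. Collagen genes of stromal cells rose, Col1a1 by 2.18 ± 0.35, Col3a1 by 1.70 ± 0.24 and Col1a2 by 1.69 ± 0.35, and so did the biliary keratin Krt19 by 2.53 ± 0.63 (adjusted p = 0.0301) and Epcam by 0.93 ± 0.23. In all, 183 genes rose and 124 fell (137 and 71 at least 2-fold).

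NRF2 targets rose in 13 of 17 in FFPE adenomas (15 adjusted over the list alone; median 1.38, adjusted p = 4.63e-40, and 0.00232 with an estimated correlation). Foci and oncofetal markers rose in 5 of 17 (6 adjusted over the list alone; adjusted p = 3e-07, and 0.0733 with an estimated correlation). Phenobarbital-responsive genes rose in 4 of 16, Aldh1a1, Ephx1, the export pump Abcc3 and Gstm1, by 0.94, 0.73, 0.63 and 0.48, without the list passing (adjusted p = 0.287, median -0.10, mean 0.01). Bile acid genes fell in 3 of 14 (8 adjusted over the list alone; adjusted p = 4.39e-08, and 0.0733 with an estimated correlation). Periportal genes fell in 3 of 16 (5 adjusted over the list alone; adjusted p = 4.55e-06, and 0.0733 with an estimated correlation), namely Sds, Gls2 and Asl by -2.08, -1.37 and -1.07. Wnt/beta-catenin targets and pericentral genes fell in 2 of 16, Cyp1a2 (-2.82 ± 0.48) and Oat (-2.46 ± 0.43), with 5 adjusted over the list alone (adjusted p = 0.000185, and 0.244 with an estimated correlation).

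Cholesterol synthesis genes fell in 3 of 13 in FFPE adenomas (6 adjusted over the list alone; adjusted p = 4.64e-06, and 0.204 with an estimated correlation). Male-predominant genes fell in 2 of 9 (5 fell and 1 rose adjusted over the list alone; adjusted p = 0.0039, and 0.145 with an estimated correlation), fatty acid oxidation genes in 2 of 14 (3 adjusted over the list alone; adjusted p = 0.00513, and 0.348 with an estimated correlation) and acute phase genes in 2 of 14 (4 adjusted over the list alone; adjusted p = 0.000625, and 0.161 with an estimated correlation). Stellate cell and fibroblast markers rose in 3 of 15 (4 adjusted over the list alone; adjusted p = 3.63e-06, and 0.105 with an estimated correlation) and cholangiocyte markers in 2 of 8 (3 adjusted over the list alone; adjusted p = 0.0066, and 0.107 with an estimated correlation). Of the proliferation genes, 0 of 24 passed in limma (0 adjusted over the list alone) and the list did not pass (median 0.31, adjusted p = 0.0651). The remaining lists, macrophage markers included (median -0.07), did not pass (adjusted p = 0.0824 to 0.948). Median and mean differed in sign for immediate early genes (0.08 and -0.01) and fatty acid synthesis (-0.06 and 0.01). Without surrounding replicate 1, 2 or 4 the count was 165, 145 or 181 in place of 307, and without adenoma replicate 2, 4 or 5 it was 176, 196 or 173.

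Adenomas were then set against foci of the same fixation, the only comparison between those lesion types (n = 5 and 9, 2 animals with both). No single gene passed (0 by limma, 633 at an unadjusted p under 0.05), and 1 did without adenoma replicate 2 or 5. Macrophage markers were higher as a list in adenomas (5 of 11 adjusted over the list alone; median 0.56, adjusted p = 5.46e-11, and 0.0325 with an estimated correlation). Adenoma replicate 5 stood apart with a macrophage score of 0.72 (nearest 0.16) and a blood cell score of 1.19 (nearest -0.27). Without it the median was 0.48 (adjusted p = 4.04e-06, and 0.118 with an estimated correlation). Stellate cell and fibroblast markers were also higher as a list (3 of 15 adjusted over the list alone; median 0.42, adjusted p = 1.94e-05, and 0.12 with an estimated correlation). Dcn stood at 1.33 ± 0.34 (adjusted p = 0.886 over all genes, group means 6.91 and 6.63). Male-predominant genes had a median of 0.35 (2 of 9 adjusted over the list alone; adjusted p = 0.00562, and 0.157 with an estimated correlation). Cyp2c11 stood at 1.13 ± 0.27 (adjusted p = 0.828 over all genes). Periportal genes (median 0.16, adjusted p = 0.00513, and 0.175 with an estimated correlation), fatty acid oxidation genes (median 0.16, adjusted p = 0.00732, and 0.366 with an estimated correlation) and inflammatory mediators (median 0.22, adjusted p = 0.00961, and 0.12 with an estimated correlation) were also higher as lists. These 3 lists and the male-predominant genes did not pass without 1 adenoma array, fatty acid oxidation and male-predominant genes without replicate 1 (medians -0.06 and 0.24, adjusted p = 0.884 and 0.187), inflammatory mediators without replicate 5 (0.14, adjusted p = 0.178) and periportal genes without replicate 2 (0.07, adjusted p = 0.112). NRF2 targets had a median of -0.12 (adjusted p = 0.0548), Gstp1 differed by -0.41 ± 0.42 and Ggt1 by -0.34 ± 0.25, and the other lists did not pass (adjusted p = 0.0651 to 0.875).

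Frozen nodules were compared with surrounding liver (n = 5 and 7, 3 animals with both). Mitotic genes were among the largest rises, with Cdk1, the kinase that starts mitosis, at 1.45 ± 0.27 (adjusted p = 0.0315), the proliferation antigen Mki67 at 1.33 ± 0.25 (adjusted p = 0.0315), the cyclin Ccnb2 at 1.18 ± 0.23 and the kinesin Kif20a at 1.04 ± 0.21. Slc1a4, a serine transporter, rose by 1.69 ± 0.35 and Psat1, which makes serine, by 1.47 ± 0.25, beside Tubb6 (1.54 ± 0.28), S100a10 (1.28 ± 0.22) and Ttc39a (1.10 ± 0.21). The 5 genes that fell were Hyal3 (-0.82 ± 0.17), Abhd1 (-0.72 ± 0.15), Psmd3 (-0.63 ± 0.10), Slc38a3 (-0.57 ± 0.11) and Ncstn (-0.47 ± 0.10). None of these genes passed in the matched fit (adjusted p = 0.113 to 0.266). Gstp1 was higher by 1.56 ± 0.34 in 3 of 3 animals and missed the threshold (adjusted p = 0.0532).

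The proliferation list rose in 4 of 24 in nodules (18 adjusted over the list alone; median 0.66, adjusted p = 5.66e-18, and 0.125 with an estimated correlation). Replicate 5 did not share the rise, with a score of -0.60 (nearest 0.29) and Mki67 at 4.43 (nearest 6.39). Without it the list median was 0.83 (adjusted p = 9.95e-22). NRF2 targets rose in 1 of 17, Ugdh (0.78 ± 0.15), with 12 adjusted over the list alone (median 0.87, adjusted p = 4.4e-11, and 0.125 with an estimated correlation). Foci and oncofetal markers were higher as a list (4 of 17 adjusted over the list alone; median 0.52, adjusted p = 0.00165, and 0.125 with an estimated correlation). Replicate 4 stood apart at a score of 1.27 (nearest 0.25), and without it the median was 0.43 (adjusted p = 0.0145). Macrophage markers were lower as a list (7 of 11 adjusted over the list alone; median -0.53, adjusted p = 2.27e-06, and 0.125 with an estimated correlation). Periportal genes (adjusted p = 0.00153), acute phase genes (adjusted p = 0.00111), bile acid genes (adjusted p = 0.00196), immediate early genes (adjusted p = 0.00201), blood cell markers (adjusted p = 0.0194), Wnt/beta-catenin targets and pericentral genes (adjusted p = 0.0265), endothelial markers (adjusted p = 0.0328) and male-predominant genes (adjusted p = 0.0437) were lower as lists, and none of these passed with an estimated correlation (adjusted p = 0.367, 0.359, 0.244, 0.269, 0.125, 0.638, 0.462 and 0.515). Plain group means gave medians of only -0.11 for immediate early, -0.06 for endothelial and -0.002 for blood cell genes, where the fit gave -0.40, -0.18 and -0.42. The other lists did not pass (adjusted p = 0.0543 to 0.923), with inflammatory mediators at a median of 1e-04 and a mean of -0.12. In all, 27 genes rose and 5 fell with animals as blocks. In the matched fit 0 passed (limma, 1200 at an unadjusted p under 0.05). Mki67 stood at 1.16 with an adjusted p of 0.172, while the proliferation and NRF2 lists kept adjusted p = 9.37e-15 and 1.31e-13. The count was also 0 without nodule replicate 1 or 2, 4 and 5 without replicates 5 and 4, and 1, 9, 7 and 12 without surrounding replicates 2, 3, 6 and 7. Without arrays of other groups in the fit it was 13 (carcinoma replicate 1), 19 and 59 (beta-catenin carcinoma replicates 2 and 4) and 81 (adenoma replicate 3).

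Frozen adenomas against surrounding liver had the most called genes of the 10 comparisons (n = 6 and 7, 2 animals with both). Mki67 rose by 2.56 ± 0.24 (adjusted p = 3.3e-06; matched fit 2.72, adjusted p = 6.77e-05), Cdk1 by 2.88 ± 0.26, the replication licensing factor Mcm6 by 2.41 ± 0.26 and the cyclin Ccna2 by 2.43 ± 0.27. The cystine importer Slc7a11 rose by 4.52 ± 0.62 (adjusted p = 4.79e-05; matched fit 4.05, adjusted p = 0.0022), Krt19 by 4.37 ± 1.02 (adjusted p = 0.00369; matched fit 4.45, adjusted p = 0.0246) and Gstp1 by 2.32 ± 0.34 (adjusted p = 8.15e-05; matched adjusted p = 0.00114). Cyp1a2 fell by 4.43 ± 0.67, Obp3 by 4.23 ± 0.77, Avpr1a by 4.02 ± 0.65, Akr1c1 by 4.00 ± 0.59 and Inmt by 3.91 ± 0.59. Their matched adjusted p were 0.00231 to 0.00727. Other large rises were those of Bex1 (4.02 ± 0.89), the protease Ctrc (3.66 ± 0.92), Aldh3a1 (3.54 ± 1.20; matched adjusted p = 0.176), Slc66a3 (3.51 ± 0.34), Pcdh17 (3.46 ± 0.42) and B3galnt1 (3.36 ± 0.53), and other large falls those of Dhrs7l1 (-3.97 ± 0.74), Cyp8b1 (-3.85 ± 0.85) and Cyp1a1 (-3.78 ± 0.44). In all, 2194 genes rose and 1361 fell (453 and 257 at least 2-fold). In the matched fit 1189 rose and 933 fell, with 1972 genes called in the same direction in both.

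The proliferation list rose in 22 of 24 in frozen adenomas (23 adjusted over the list alone, 20 in the matched fit; median 1.23, adjusted p = 2.61e-16, and 0.125 with an estimated correlation). NRF2 targets rose in 13 of 17 (14 adjusted over the list alone, 12 matched; median 1.43, adjusted p = 3.79e-09, and 0.168 with an estimated correlation). Foci and oncofetal markers rose in 5 of 17 and fell in 1 (7 and 1 adjusted over the list alone; adjusted p = 0.00546, and 0.157 with an estimated correlation), the rises including Cdkn3 (2.25 ± 0.33) and Sox4 (1.66 ± 0.19). The fall was that of Igf2, a fetal growth factor, by 0.51 ± 0.17 (matched adjusted p = 0.172). Glycolysis genes rose in 5 of 12, among them Aldoa (0.96 ± 0.22) and Hk1 (1.51 ± 0.44; matched adjusted p = 0.0584), with 5 also adjusted over the list alone (adjusted p = 0.0293, and 0.26 with an estimated correlation). Fatty acid synthesis genes rose in 4 of 15, the elongase Elovl6 (2.28 ± 0.50), the desaturase Scd (1.95 ± 0.49; matched adjusted p = 0.0535) and Me1 (1.43 ± 0.29) among them, and fell in 1, Fads2 (-1.59 ± 0.32), without the list passing (adjusted p = 0.584).

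Bile acid genes fell in 11 of 14 in frozen adenomas (12 adjusted over the list alone, 9 matched; median -1.27, adjusted p = 3.93e-08, and 0.0733 with an estimated correlation). They included Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-1.93 ± 0.67; matched adjusted p = 0.197). Male-predominant genes fell in 9 of 9 (4 matched; median -1.96, adjusted p = 4.82e-06, and 0.159 with an estimated correlation). Cyp2c11 stood at -1.98 ± 0.59 (matched adjusted p = 0.0983). Wnt/beta-catenin targets and pericentral genes fell in 7 of 16 (2 matched; median -0.91, adjusted p = 0.00015, and 0.417 with an estimated correlation). Oat stood at -2.19 ± 0.54 (matched adjusted p = 0.0706), Cyp2e1 at -1.93 ± 0.40 and the regulator Tbx3 at -1.85 ± 0.54 (matched adjusted p = 0.0991). Periportal genes fell in 6 of 16 (8 adjusted over the list alone, 3 matched; adjusted p = 0.000323, and 0.309 with an estimated correlation). Cholesterol synthesis genes fell in 7 of 13 (9 adjusted over the list alone, 6 matched; adjusted p = 0.000379, and 0.284 with an estimated correlation). Fatty acid oxidation genes fell in 5 of 14 (6 adjusted over the list alone; adjusted p = 0.00165, and 0.283 with an estimated correlation).

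Cholangiocyte markers rose in 2 of 8 in frozen adenomas, Krt19 and Epcam (1.40 ± 0.28), with 3 adjusted over the list alone (median 1.45, adjusted p = 0.0182, and 0.502 with an estimated correlation). Macrophage markers fell in 4 of 11 (adjusted p = 0.0136, and 0.369 with an estimated correlation; matched adjusted p = 0.116). Hepatocyte markers fell in 5 of 11, Rbp4 (-0.32 ± 0.06) among them, and rose in 1, Apoa1 (1.13 ± 0.27; matched adjusted p = 0.0573), with a lower list (adjusted p = 0.0205, and 0.157 with an estimated correlation). Acute phase genes fell in 2 of 14 (adjusted p = 0.0256, and 0.522 with an estimated correlation; matched adjusted p = 0.115). Stellate cell and fibroblast markers rose in 2 of 15, Lox (2.44 ± 0.69) and Timp1 (1.26 ± 0.35), without the list passing (adjusted p = 0.326). The phenobarbital list (2 of 16 rose, 3 fell, Cyp3a9 at -2.49 ± 0.65 and Cyp2c7 at -2.42 ± 0.61 among them) and the inflammatory, immediate early, endothelial, lymphocyte and blood cell lists did not pass (adjusted p = 0.131 to 0.948). The medians of immediate early genes and lymphocyte markers were above 0 where the test pointed down. Without animal 23 the count fell from 3555 to 570, and without animal 14 to 2247.

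**Figure D2:**
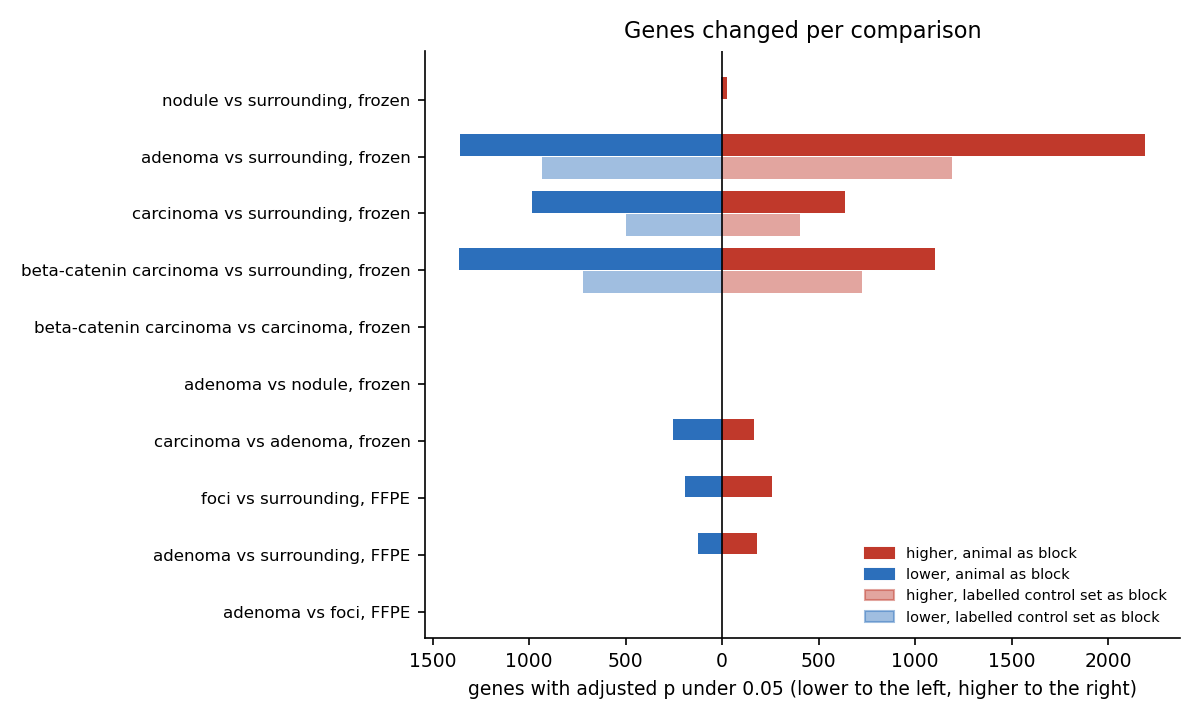
Number of genes with an adjusted p under 0.05 that were higher (right) or lower (left) in the first group named, per comparison, with the animal as block (solid) and, for frozen tissue, the labelled control set as block (pale). Frozen adenomas against surrounding liver have the most called genes with the animal as block (2194 higher and 1361 lower), and carcinomas against adenomas have 0 with the control set as block.

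Carcinomas without a labelled mutation were compared with surrounding liver (n = 4 and 7, 3 animals with both). Bex1 rose by 5.73 ± 0.96 (adjusted p = 0.000824; matched fit 5.67, adjusted p = 0.00784), Aldh3a1 by 4.36 ± 1.29 (adjusted p = 0.0322; matched adjusted p = 0.0909), Epdr1 by 3.78 ± 0.87 and Slc7a11 by 3.11 ± 0.66. Obp3 fell by 4.38 ± 0.83, Inmt by 3.78 ± 0.63, Cyp1a1 by 3.76 ± 0.48, Car3 by 3.38 ± 0.69 and Hsd3b5 by 3.31 ± 0.57. Their matched adjusted p were 0.00288 to 0.0263. Gstp1 rose by 1.83 ± 0.36 (adjusted p = 0.00256; matched fit 1.73, adjusted p = 0.0223) and Mki67 by 1.51 ± 0.26 (adjusted p = 0.00103; matched fit 1.56, adjusted p = 0.00497). Other large rises were those of Ugt2b7 (3.50 ± 1.04), Cracdl (3.39 ± 0.82), Klhl14 (3.23 ± 0.81), whose matched adjusted p were 0.122, 0.0643 and 0.0643, and Bend5 (3.22 ± 0.68), and other large falls those of Tpd52l1 (-3.54 ± 0.61), Avpr1a (-3.34 ± 0.70) and AKR1C3l1 (-3.27 ± 0.59). In all, 637 genes rose and 983 fell (166 and 205 at least 2-fold), and in the matched fit 406 rose and 498 fell, 766 in both.

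NRF2 targets rose in 13 of 17 in carcinomas (14 adjusted over the list alone, 10 matched; median 1.19, adjusted p = 6.73e-13, and 0.12 with an estimated correlation). Proliferation genes rose in 11 of 24 (13 adjusted over the list alone, 8 matched; adjusted p = 5.46e-11, and 0.212 with an estimated correlation). Foci and oncofetal markers rose in 5 of 17 and fell in 1, Igf2 (-0.58 ± 0.19), and the list passed with animals as blocks only (adjusted p = 0.0259, and 0.244 with an estimated correlation; matched adjusted p = 0.136). Glycolysis genes rose in 3 of 12, Gpi (1.21 ± 0.27), Aldoa (1.06 ± 0.23; matched adjusted p = 0.0601) and Eno1 (1.01 ± 0.23; matched adjusted p = 0.0658), with 5 rising and 1 falling adjusted over the list alone (adjusted p = 0.00163, and 0.125 with an estimated correlation). Fatty acid synthesis genes rose in 5 of 15 and fell in 1, with Scd at 2.27 ± 0.53, the fatty acid synthase Fasn at 1.47 ± 0.32 and Me1 at 1.47 ± 0.31, without the list passing (adjusted p = 0.0526).

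Periportal genes fell in 5 of 16 in carcinomas (7 adjusted over the list alone, 4 matched; median -0.84, adjusted p = 1.5e-05, and 0.244 with an estimated correlation). Bile acid genes fell in 8 of 14 (8 adjusted over the list alone, 6 matched; adjusted p = 4.85e-06, and 0.122 with an estimated correlation). Fatty acid oxidation genes fell in 6 of 14 (adjusted p = 0.000684, and 0.26 with an estimated correlation). Cholesterol synthesis genes fell in 3 of 13 (5 adjusted over the list alone; adjusted p = 0.0048, and 0.393 with an estimated correlation), male-predominant genes in 3 of 9 (8 adjusted over the list alone; adjusted p = 7.63e-05, and 0.217 with an estimated correlation) and acute phase genes in 3 of 14, the fibrinogen chains Fga, Fgb and Fgg, the last with a matched adjusted p of 0.0522 (adjusted p = 0.00708, and 0.446 with an estimated correlation). Macrophage markers fell in 4 of 11 (6 adjusted over the list alone, 7 matched; adjusted p = 0.000127, and 0.199 with an estimated correlation). The Wnt/beta-catenin list had 1 of 16 called, Cyp1a2 (-2.79 ± 0.72), and did not pass (median 0.17, mean -0.06, adjusted p = 0.596), and the other lists did not either (adjusted p = 0.142 to 0.86). Phenobarbital-responsive genes had a median of -0.01 and a mean of -0.17 where the test pointed up. Without replicate 1 the count of called genes was 728 and without replicate 4 it was 665, in place of 1620.

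Carcinomas labelled with a beta-catenin mutation were compared with the same surrounding liver (n = 4 and 7, 3 animals with both). The Wnt targets Lgr5, a stem cell receptor, and Axin2, a feedback inhibitor, rose by 2.53 ± 0.63 (adjusted p = 0.00794; matched adjusted p = 0.0452) and 1.83 ± 0.46 (adjusted p = 0.00847; matched adjusted p = 0.0793), each in 2 of 3 animals, and the Wnt inhibitor Apcdd1 by 1.68 ± 0.33 in 3 of 3. Bex1 rose by 6.19 ± 0.92 (adjusted p = 0.000122; matched fit 6.11, adjusted p = 0.00306), beside Bex4 (3.38 ± 1.05; matched adjusted p = 0.157), Bex3 (3.05 ± 0.33) and Tceal9 (3.03 ± 0.33), which belong to the same gene family. Obp3 fell by 5.62 ± 0.79, Car3 by 4.76 ± 0.67, Aass by 4.69 ± 0.86, Hsd3b5 by 4.56 ± 0.55 and Cyp2c7 by 4.44 ± 0.63. Their matched adjusted p were 0.000459 to 0.00595. Other large rises were those of Slc25a4 (4.02 ± 0.59), Mmp12 (3.01 ± 0.36), Epdr1 (2.89 ± 0.83; matched adjusted p = 0.0833) and Rragd (2.85 ± 0.63), and other large falls those of Akr1b7 (-4.17 ± 0.44), Kcnj15 (-4.06 ± 0.37) and Mup5 (-4.03 ± 0.43). Mki67 rose by 2.04 ± 0.25 and Gstp1 by 1.66 ± 0.35. In all, 1101 genes rose and 1362 fell (216 and 281 at least 2-fold), and in the matched fit 723 rose and 721 fell, 1242 in both.

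The Wnt/beta-catenin list rose in 5 of 16 in these carcinomas (6 adjusted over the list alone, 2 matched; median 0.76, adjusted p = 0.00354, and 0.531 with an estimated correlation; matched adjusted p = 0.0594), and Glul, glutamine synthetase, had 1.88 ± 0.70 (adjusted p = 0.0693). Without replicate 4 the list median was 0.50 (adjusted p = 0.0813). Periportal genes fell in 9 of 16 (14 adjusted over the list alone, 8 matched; median -1.11, adjusted p = 3.02e-08, and 0.145 with an estimated correlation). NRF2 targets rose in 12 of 17 (15 adjusted over the list alone, 6 matched; adjusted p = 1.1e-08, and 0.18 with an estimated correlation) and proliferation genes in 17 of 24 (21 adjusted over the list alone, 11 matched; adjusted p = 2.29e-11, and 0.202 with an estimated correlation). Cholesterol synthesis genes fell in 9 of 13 (11 adjusted over the list alone, 8 matched; adjusted p = 2.92e-08, and 0.125 with an estimated correlation). Fatty acid synthesis genes rose in 2 of 15 and fell in 4, the desaturases Fads2 (-1.32 ± 0.33) and Fads1 (-0.71 ± 0.14) among them (adjusted p = 0.276). Bile acid genes fell in 9 of 14 (7 matched; adjusted p = 2.52e-06, and 0.12 with an estimated correlation), fatty acid oxidation genes in 7 of 14 (8 adjusted over the list alone; adjusted p = 0.000196, and 0.242 with an estimated correlation) and male-predominant genes in 4 of 9 (adjusted p = 0.000181, and 0.244 with an estimated correlation). Cyp2c11 stood at -3.01 ± 0.61.

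Acute phase genes fell in 8 of 14 in beta-catenin carcinomas (9 fell and 1 rose adjusted over the list alone, 7 matched; adjusted p = 0.000211, and 0.284 with an estimated correlation). Foci and oncofetal markers rose in 5 of 17 and fell in 1 (adjusted p = 0.0296, and 0.257 with an estimated correlation; matched adjusted p = 0.138; without replicate 1 median 0.15, adjusted p = 0.301), and glycolysis genes rose in 3 of 12 (adjusted p = 0.0256, and 0.257 with an estimated correlation; matched adjusted p = 0.105). Macrophage markers fell in 6 of 11 (7 adjusted over the list alone, 7 matched; adjusted p = 9.57e-05, and 0.19 with an estimated correlation). Hepatocyte markers fell in 3 of 11 (adjusted p = 0.0293, and 0.18 with an estimated correlation). Stellate cell markers did not pass as a list (adjusted p = 0.242). The phenobarbital, inflammatory, immediate early, endothelial, cholangiocyte, lymphocyte and blood cell lists did not pass (adjusted p = 0.0505 to 0.715). Phenobarbital-responsive genes had a median of 0.06 and a mean of -0.23. Without replicate 3 the count was 1640 in place of 2463, and without animal 23 it was 734.

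The carcinoma groups were compared with each other to ask what goes with the labelled mutation (n = 4 and 4, 3 animals with both). Beta-catenin target levels did not follow the labels in every lesion. Glul was 13.32, 12.96 and 13.31 in beta-catenin carcinoma replicates 2 to 4 and 9.26 in replicate 1, against 9.56 and 10.39 in carcinoma replicates 2 and 4 and 13.02 and 12.69 in replicates 1 and 3, which carry no mutation label. Axin2 and Lgr5 followed the same pattern, with Lgr5 at 3.08 in beta-catenin carcinoma replicate 1 and at 5.84 and 6.17 in carcinoma replicates 1 and 3. Surrounding liver lay between 9.91 and 10.80 for Glul. No gene passed between the groups (0 by limma, 723 at an unadjusted p under 0.05; matched fit 0 and 812).

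As lists, cholesterol synthesis genes were lower in beta-catenin carcinomas (5 of 13 adjusted over the list alone; median -0.41, adjusted p = 7.44e-11, and 0.105 with an estimated correlation; matched adjusted p = 1.55e-10). Fatty acid synthesis genes were lower (2 of 15 adjusted over the list alone; median -0.59, adjusted p = 3.82e-10, and 0.125 with an estimated correlation; matched adjusted p = 1.64e-09). The Wnt/beta-catenin list was higher (median 0.82, adjusted p = 2.92e-06, and 0.317 with an estimated correlation). Tbx3 stood at 1.59 ± 0.62 and Lgr5 at 1.38 ± 0.70 (adjusted p = 0.824 and 0.999). Periportal genes (median -0.46, adjusted p = 0.000255), acute phase genes (median -0.20, adjusted p = 0.00455) and NRF2 targets (median -0.26, adjusted p = 0.0256) were lower and cholangiocyte markers higher (median 0.55, adjusted p = 0.0118), and none passed with an estimated correlation (adjusted p = 0.299, 0.417, 0.582 and 0.462). The cholangiocyte score was 1.74 in beta-catenin carcinoma replicate 1 and at most -0.45 in the other 3. Without replicate 1 the list had a median of 0.12 and did not pass (adjusted p = 0.946). NRF2 targets did not pass without replicate 4 (median 0.06, adjusted p = 0.818), nor periportal and acute phase genes without replicate 2 (adjusted p = 0.514 and 0.295). The other lists did not pass (adjusted p = 0.0937 to 0.801). Median and mean differed in sign for blood cell markers (0.005 and -0.04), phenobarbital-responsive genes (0.07 and -0.06) and foci markers (-0.01 and 0.04). Without beta-catenin carcinoma replicate 1, 10 genes passed (6 rose, 4 fell), and without replicate 2, 5 passed.

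**Figure D3:**
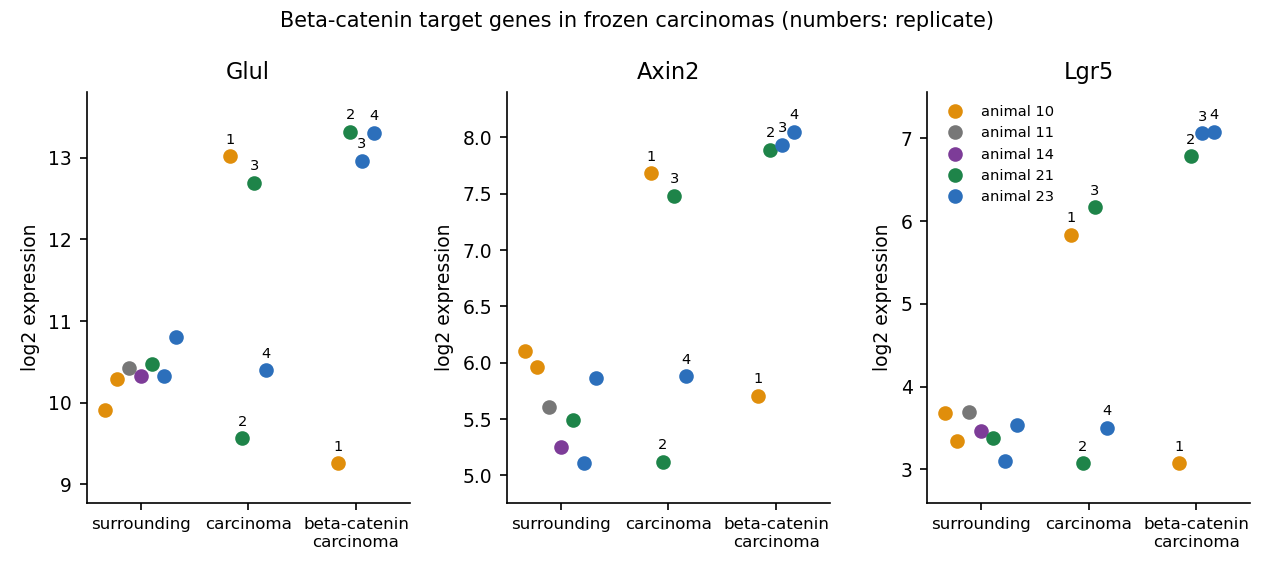
Log2 expression of the beta-catenin targets Glul, Axin2 and Lgr5 in surrounding liver and in each carcinoma (points, coloured by animal, with the replicate number). Beta-catenin carcinoma replicate 1 lies at 9.26 for Glul and carcinoma replicates 1 and 3 at 13.02 and 12.69, against their group labels.

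Frozen adenomas were compared with nodules (n = 6 and 5, 1 animal with both). The proliferation list was higher in adenomas (10 of 24 adjusted over the list alone; median 0.61, adjusted p = 1.06e-09, and 0.244 with an estimated correlation; matched adjusted p = 3.6e-13). Cdk1 stood at 1.43 ± 0.32 and Mki67 at 1.23 ± 0.29 (adjusted p = 0.0751 and 0.0844 over all genes). Nodule replicate 5, the only one of animal 14, had Mki67 at 4.43 (other nodules from 6.39). Without it the list median was 0.37 (adjusted p = 7.34e-05, and 0.434 with an estimated correlation). Bile acid genes were lower (9 of 14 adjusted over the list alone; median -0.87, adjusted p = 8.1e-08, and 0.0796 with an estimated correlation; matched adjusted p = 7.55e-07). Male-predominant genes were lower (7 of 9 adjusted over the list alone; median -1.41, adjusted p = 2.31e-06, and 0.147 with an estimated correlation; matched adjusted p = 2.95e-06). Plain group means differed by medians of only -0.20 for male-predominant and 0.19 for proliferation genes, so most of both shifts comes from the adjustment for animals, of which only animal 14 holds both tissues. The same holds for fatty acid oxidation and immediate early genes below (plain medians -0.04 and 0.02). NRF2 targets (median 0.55, adjusted p = 0.000206) were higher, and Wnt/beta-catenin targets (median -0.62, adjusted p = 0.000477), cholesterol synthesis (median -0.41, adjusted p = 0.00015) and fatty acid oxidation genes (median -0.31, adjusted p = 0.00351) lower, none with an estimated correlation (adjusted p = 0.366, 0.464, 0.266 and 0.317). Immediate early genes, stellate cell markers, glycolysis and cholangiocyte markers shifted up (medians 0.51, 0.71, 0.22 and 0.75, adjusted p = 0.0294, 0.0371, 0.0372 and 0.0425, and 0.441, 0.637, 0.269 and 0.548 with an estimated correlation). Periportal genes shifted down (adjusted p = 0.0173, and 0.515 with an estimated correlation). The other lists did not pass (adjusted p = 0.0708 to 0.925), acute phase genes with a median of -0.07 and a mean of 0.11, and blood cell markers with a median of 0.04 where the test pointed down. No single gene passed (0 by limma, 2265 at an unadjusted p under 0.05; matched fit 0 and 1727), and without adenoma replicate 2, 214 genes did (102 rose, 112 fell), with 81, 64, 21, 3 and 1 without adenoma replicate 5, nodule replicate 4, adenoma replicates 4 and 3 and beta-catenin carcinoma replicate 3.

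Carcinomas were compared with adenomas (n = 4 and 6, 1 animal with both). With animals as blocks Cyp8b1 rose by 4.10 ± 1.06 (adjusted p = 0.042; matched fit 3.23, adjusted p = 0.929), Gstm2 by 2.13 ± 0.47 (matched 0.63), Ppp2r1a by 2.01 ± 0.40 (matched 0.41), Acox3 by 1.99 ± 0.52 (matched 0.12) and Gulo by 1.94 ± 0.45 (matched 1.17). Ampd3 fell by 2.91 ± 0.76, St14 by 2.34 ± 0.59, Abtb3 by 1.98 ± 0.39, Fam110c by 1.76 ± 0.39, Cdk1 by 1.65 ± 0.33 (adjusted p = 0.0265) and Mcm6 by 1.54 ± 0.32, with matched changes of -2.70, -2.04, -1.77, -1.51, -1.45 and -1.36. None of these genes passed in the matched fit (adjusted p = 0.929 to 0.971). In all, 166 genes rose and 253 fell. In the matched fit 0 passed (limma, 711 at an unadjusted p under 0.05), and the surrounding arrays of the carcinoma control sets differed from the other surrounding arrays in the same direction for 96.4% of the 419 genes. The count was 0 also without carcinoma replicate 1 or 4 or adenoma replicate 6, 4 without nodule replicate 5, 87, 166 and 252 without beta-catenin carcinoma replicates 2 to 4, 215 without adenoma replicate 5, and 223, 279 and 632 without nodule replicates 1 and 2 and surrounding replicate 2. After quantile normalization the split was 194 rises and 158 falls.

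Proliferation genes were lower in carcinomas than in adenomas (3 of 24 called, 13 adjusted over the list alone, 0 matched; median -0.62, adjusted p = 1.86e-06, and 0.345 with an estimated correlation; matched adjusted p = 3.79e-08). Plain group means differed by a median of only -0.20, and only animal 23 holds both tissues, so most of this shift comes from the adjustment for animals. The Wnt/beta-catenin list was higher (1 of 16 adjusted over the list alone; median 1.23, adjusted p = 9.93e-08, and 0.266 with an estimated correlation; matched median 0.77, adjusted p = 0.000474). Its score was 0.993 and 0.75 in carcinoma replicates 1 and 3 and -0.848 and -0.553 in replicates 2 and 4. Without replicate 1, whose label is in doubt, the median was 0.66 (adjusted p = 9.76e-05). Axin2 stood at 1.67 ± 0.56 (adjusted p = 0.0917 over all genes). Cholangiocyte markers were lower (median -1.20, adjusted p = 0.0265, and 0.515 with an estimated correlation; matched adjusted p = 0.000792). Krt19 stood at -3.70 ± 1.27 (adjusted p = 0.102). Phenobarbital-responsive genes were higher with animals as blocks (median 0.22, adjusted p = 0.029, and 0.269 with an estimated correlation; matched adjusted p = 0.571). The glycolysis enzyme Gpi (1.25 ± 0.31), Crp (1.56 ± 0.37) and Cyp8b1 were the called members of their lists, which did not pass, and neither did the others (adjusted p = 0.0947 to 0.918). The sign of the median differed from that of the test for glycolysis (-0.11), stellate cell markers (-0.05) and fatty acid oxidation (-0.08), and from that of the mean for blood cell markers (0.08 and -0.17).

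Adenomas were measured in both fixations with separate surrounding samples, which asks whether frozen and FFPE tissue show the same changes. Only animal 14 gave adenomas to both, so differences between the fixations are mixed with those between animals. Of the 3555 genes called in frozen adenomas, 2779 (78.2%) had the same sign in FFPE adenomas, and of the 307 called in FFPE adenomas, 300 (97.7%) had the same sign in frozen ones. Both fits called 242 genes, 240 of them in the same direction, where independent lists would share 40.1. The log2 changes correlated across genes with r = 0.529, though genes are not independent replicates, and tumours 4 and 5 of animal 14 were measured both ways. Without them the same-sign share was 75.6%. For 1727 genes (12.1%) the probe set differed between the fixations, and with those of the frozen fit in both the share was 78.2% and r = 0.528. Proliferation genes rose in 22 of 24 in frozen and in 0 of 24 in FFPE adenomas, and a joint fit of both fixations gave a list difference with a median of 1.22 (adjusted p = 3.35e-15, and 0.0424 with an estimated correlation), with Mki67 differing by 1.62 (adjusted p = 0.147).

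**Figure D4:**
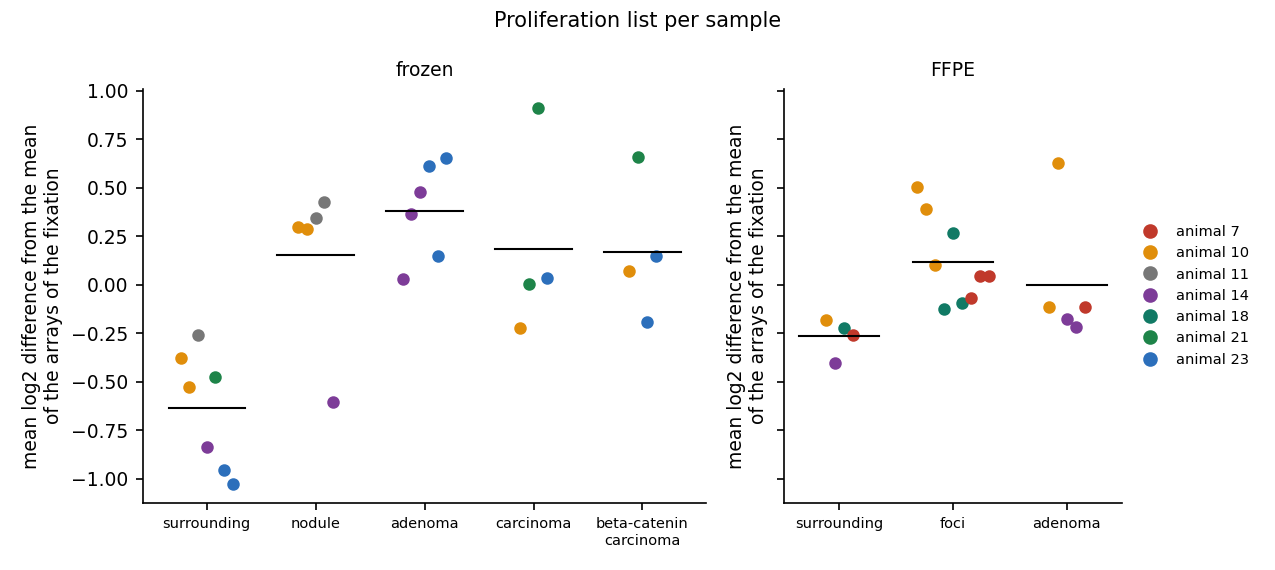
Score of the proliferation list per array (points, coloured by animal; mean log2 difference of its 24 genes from the mean of the arrays of that fixation) with group means (lines). Of the frozen nodules, replicate 5 lies lowest at -0.60, and of the FFPE adenomas, replicate 2 lies highest at 0.63.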

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

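The tests of swapped labels in animal 21, of the batch of control sets, of the same tumours in both fixations and of NRF2 targets as a measure of lost changes were chosen only after the results were seen, as were the joint fit of both fixations, the frozen probe sets in FFPE tissue and the splits within animals.

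Of the carcinomas with the mutation label, replicate 1 (animal 10) stood apart in beta-catenin targets, with Glul at 9.26, Axin2 at 5.7 and Lgr5 at 3.08, where the nearest of the other 3 had 12.96, 7.89 and 6.78, and its Cyp7a1 of 8.14 and cholangiocyte score of 1.74 also lay apart (nearest 10.92 and -0.45). Carcinoma replicate 1 of the same animal has no mutation label and a Wnt list score of 0.993 against -0.771 in the labelled lesion. Over 100 genes that part the carcinoma groups in other animals, 77% differed between these 2 in the direction of a swap, against 52% to 63% in 8 same-animal pairs of adenomas or nodules. Without carcinoma pairs this cannot part a swap from unlabelled beta-catenin activity, and a swap stays open. Such activity, an explanation from biology, would give the 0.993 and the 0.75 of carcinoma replicate 3 (animal 21), which a swap leaves unexplained, but not the low score of the labelled lesion. A single wrong label there was not tested. Surrounding liver in the labelled sample is argued against, because its changes followed those of other carcinomas with a slope of 0.771 over 509 genes (0.848 in carcinoma replicate 1), and a swap in animal 21 is argued against by a score of 1.05 in its labelled lesion.

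Carcinomas differed from adenomas in 419 genes with animals as blocks and in 0 in the matched fit (limma, 711 at an unadjusted p under 0.05, where chance gives 710.8). Surrounding arrays of the carcinoma control sets differed from the other surrounding arrays in 875 genes, and 96.42% of the 419 genes differed in the same direction there (71.46% of all genes), as a batch of control sets would give. The median change of the 419 genes was 0.732 with a standard error of 0.177, and 0.346 with 0.197 in the matched fit, with the same sign in 99.52%. A batch, which is drawn from control set names since the labels give none, fits these values, and the proliferation list decides little, with a median of -0.108 between batches, -0.58 between the tumours in the matched fit (adjusted p = 3.79e-08, and 0.276 with an estimated correlation) and -0.20 in plain group means. A real difference between the tumour types stays open, because only animal 23 holds both and its lesions belong to different control sets.

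Proliferation genes had a median rise of 1.229 in frozen and 0.308 in FFPE adenomas, and a joint fit gave a difference of 1.222 (adjusted p = 3.35e-15, and 0.0424 with an estimated correlation). Tumours 4 and 5 of animal 14 differed by 0.975 and 1.133 between fixations, and the FFPE piece of tumour 5 correlated best with its own frozen piece (0.368, others 0.273 and 0.233) but has a source name that reads surrounding tissue, while that of tumour 4 correlated less with its own frozen piece (0.213) than with tumours 3 and 5 (0.25 and 0.296), so different tumours in the fixations stay open. A loss of all changes is argued against by NRF2 targets with a ratio of FFPE to frozen change of 0.965, and a loss at all levels by a ratio of 0.739 for 196 genes with an FFPE level of 8 or more. Weaker measurement of low-level transcripts fits, since 367 other genes of like level and frozen change had a ratio of 0.276 against 0.25 for the list (0.234 with the frozen probe sets), though they were chosen on their frozen change, which lowers the ratio. Different parts of a tumour, whole pieces against microdissected areas, were not tested.

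Adenoma changes also differed between fixations in 7 other lists, given as the median of frozen minus FFPE. These were male-predominant genes (-1.525, adjusted p = 2.03e-07), bile acid genes (-0.42, adjusted p = 0.000215), phenobarbital-responsive genes (-0.271, adjusted p = 0.00166), macrophage markers (-0.582, adjusted p = 0.0069), Wnt/beta-catenin targets (-0.525, adjusted p = 0.00793), periportal genes (-0.281, adjusted p = 0.0477) and cholangiocyte markers (0.801, adjusted p = 0.0477), and none passed with an estimated correlation (adjusted p = 0.0653 to 0.588). Over single genes, 34 had a higher and 13 a lower change in frozen adenomas, and 1653 differed at an unadjusted p under 0.05.

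A sample far from the others of its group was found in 35 of 336 sets of samples, where chance gives about 1 in 20 (5%). Of the FFPE foci, replicate 5 had the lowest Ggt1 (8.68, nearest 9.61), replicate 8 the highest H19 (6.72, nearest 5.28), replicate 1 the highest glycolysis score (0.25, nearest 0.09) and replicate 6 the lowest mean correlation with other arrays (0.921, nearest 0.932). Nodule replicate 4 had the highest Krt19 (10.60, nearest 7.85), cholangiocyte score (1.79, nearest 0.19), foci and oncofetal score (1.27, nearest 0.25), H19 (6.80, nearest 5.76), Lgr5 (3.87, nearest 3.46) and Ctnnb1 (12.21, nearest 11.92) and the lowest array correlation (0.966, nearest 0.976). Nodule replicate 5 had the lowest Mki67 (4.43, nearest 6.39), Top2a (5.32, nearest 6.20) and proliferation score (-0.60, nearest 0.29), replicate 3 the lowest Tbx3 (5.55, nearest 6.14) and replicate 1 the lowest Alb (15.05, nearest 15.09).

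Of the frozen surrounding samples, replicate 3 had the highest H19 (5.81, nearest 5.5), and replicate 5 the highest NRF2 score (-0.15, nearest -0.75) and interquartile range (3.46, nearest 3.35). Of the FFPE surrounding samples, replicate 4 had the highest Mki67 (5.05, nearest 3.71), replicate 1 the highest foci and oncofetal score (-0.25, nearest -0.94) and replicate 2 the lowest immediate early score (-0.44, nearest 0.17). FFPE adenoma replicate 5 had the highest macrophage (0.72, nearest 0.16) and blood cell scores (1.19, nearest -0.27), replicate 2 the highest proliferation score (0.63, nearest -0.11), and replicate 4, whose source name reads surrounding tissue, the lowest phenobarbital score (-0.35, nearest -0.02) and array correlation (0.886, nearest 0.93). Carcinoma replicate 3 had the highest fatty acid synthesis score (0.86, nearest 0.50) and the lowest array correlation (0.968, nearest 0.973), and beta-catenin carcinoma replicate 4 had the lowest glycolysis score (-0.22, nearest 0.20). The frozen C43 arrays, which entered no comparison, had male-predominant scores of 2.34 and 2.31, above the highest surrounding array (2.19).

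Splits of the same arrays, the real one included, ignore the animals and leave chance between rats open. The real one called most genes for frozen adenomas (3555, highest other 2626, 1 of 100 splits as large), carcinomas (1620, highest other 463, 1 of 100), beta-catenin carcinomas (2463, highest other 395, 1 of 100) and FFPE foci (452, highest other 5, 1 of 100) against surrounding liver. Chance stays open for nodules (32, highest other 124, 2 of 100), where the matched fit called 0. The same splits gave 1 of 100 for carcinomas against adenomas (419, highest other 373) and 2 of 100 for FFPE adenomas (307, highest other 346), but splits within animals are too few there, and the matched fit called 0 genes for the former. In the split with 124 genes, all 3 arrays of animal 11 shared a group and so added nothing. The cause was not tested. The splits with 2626, 373 and 346 genes kept the real groups apart but for 1 or 2 arrays in each. The same-sign share of frozen adenoma calls in FFPE adenomas was 78.17% against a highest other of 76.71%, with 1 of 100 splits that ignore the animals as large, and splits within animals are too few (18, highest other 74.18%).

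For the comparisons with 0 genes any split calls as many, so the 35 of 35 splits between the carcinoma groups (highest other 198), 100 of 100 between adenomas and nodules (highest other 1300) and 100 of 100 between FFPE adenomas and foci (highest other 1) decide nothing about chance. The 1300 genes set nodules 1, 2, 3 and 5 with adenomas 4 and 5 against nodule 4 with adenomas 1, 2, 3 and 6, and the 198 genes set beta-catenin carcinomas 2, 3 and 4 with carcinoma 3 against the other carcinomas. Both were picked as the highest of the splits, and a structure of the samples behind them was not tested. Among splits within animals, the real one called the most genes for nodules (32, highest other 1 of 36 splits), frozen adenomas (3555, highest other 907 of 40), carcinomas (1620, highest other 2 of 27), beta-catenin carcinomas (2463, highest other 213 of 36) and foci (452, highest other 4 of 64). The splits within animals are too few for a share under 0.05 for FFPE adenomas (18 splits, 307 genes, highest other 50), carcinomas against adenomas (4 splits, 419, highest other 1) and the carcinoma groups (18 splits, 0, highest other 123).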

How the results depend on the processing

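The fits with the batch of control sets as a block, with the arrays of 1 batch and without both carcinomas of animal 10, the same-sign share in the matched fit and with the frozen probe sets, and the list tests with 1 array left out were chosen only after the data were seen. None of the 362 calls of named genes reversed its direction in any alternative run, while of 761 named genes in frozen comparisons 18, none of them called, turned in the matched fit. Of the 362 calls, 353 were kept after quantile normalization, 351 after median centring, 354 with array weights, 328 with the mean of all probe sets, 307 without the block, 271 with means per animal, 259 with a 2-fold minimum, 141 of 246 with 1 batch and, of the 261 in frozen tissue, 192 with animal and batch as blocks and 179 in the matched fit. For nodules and for carcinomas against adenomas, 0 of 15 calls were kept throughout. The alternatives not run are another pseudocount, because values are on a log2 scale, and RNA quality from control probe sets. The self-test recovered 85.1% of 2-fold changes for nodules and 29.9% for foci, and the part of signal intensity in this was not tested. Counts that moved are given below as genes called, and the cause was not tested unless fewer samples or a 2-fold minimum made it.

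Without the animal as a block in the model, the count was 93 for nodules (32 with it), 161 for FFPE adenomas (307), 437 for adenomas against nodules (0) and 2322 for carcinomas against adenomas (419), and with the animal as a random block 102, 265 and 2047 for nodules, adenomas against nodules and carcinomas against adenomas. The block moved no other count over 1.5 times. The control set as a block gave 0 for nodules, 2122 for adenomas, 904 for carcinomas, 1444 for beta-catenin carcinomas and 0 for carcinomas against adenomas. Animal and batch as blocks gave 2 for nodules, 977 for carcinomas, 1523 for beta-catenin carcinomas and 0 for carcinomas against adenomas, and arrays of 1 batch gave 0 for nodules, 1749 for adenomas, 571 for carcinomas and 993 for beta-catenin carcinomas. The mean per animal and group gave 3 for nodules, 1835 for frozen adenomas, 12 for adenomas against nodules and 5 for carcinomas against adenomas.

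Nodules gave 57 genes after quantile normalization, 17 after median centring and 60 without the lowest 25% of genes. Array weights gave 541 for nodules, 2625 for carcinomas, 1661 for adenomas against nodules and 1332 for carcinomas against adenomas. A change of at least 2-fold left 12 for nodules, 710 for frozen adenomas, 371 for carcinomas, 497 for beta-catenin carcinomas, 103 for carcinomas against adenomas and 262 for foci. Without animal 21 the counts were 10 for nodules, 1045 for carcinomas, 1 between the carcinoma groups and 192 for carcinomas against adenomas. Without beta-catenin carcinoma replicate 1, 10 genes differed between the carcinoma groups, and without both carcinomas of animal 10 the counts were 18 there, 5 for nodules, 756 for carcinomas and 0 for carcinomas against adenomas. With the C43 arrays added to surrounding liver they were 380 for nodules, 3081 for carcinomas, 354 for adenomas against nodules, 2205 for carcinomas against adenomas and 200 for FFPE adenomas. FFPE adenomas gave 196 without replicate 4.

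Of the 103 list shifts, 4 were called with an estimated correlation, 97 after quantile normalization, 103 of 105 after median centring, 87 of 100 without the block and 88 of 102 in the matched fit, and none turned. With each array of the compared groups left out in turn, 70 passed throughout and 33 did not, 2 of which turned in the test, the cholangiocyte markers (without beta-catenin carcinoma replicate 1) and NRF2 targets (without replicate 4) between the carcinoma groups. These calls follow with their highest adjusted p.

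Between the carcinoma groups these were cholangiocyte markers (0.946), NRF2 targets (0.818), periportal (0.514) and acute phase genes (0.295), in nodules Wnt/beta-catenin targets (0.164), male-predominant genes (0.142) and endothelial markers (0.0896), and between adenomas and nodules stellate cell (0.282) and cholangiocyte markers (0.192), periportal (0.18) and immediate early genes (0.0894) and glycolysis (0.0817). In frozen adenomas these were glycolysis (0.0757), acute phase genes (0.0668), cholangiocyte (0.0547) and macrophage markers (0.051), and in carcinomas acute phase genes (0.105) and foci markers (0.0746). In beta-catenin carcinomas these were foci markers (0.301, without replicate 1), Wnt/beta-catenin targets (0.0813, without replicate 4), hepatocyte markers (0.0662) and glycolysis (0.0649), and between carcinomas and adenomas phenobarbital-responsive genes (0.136) and cholangiocyte markers (0.0617). In foci these were phenobarbital-responsive genes (0.131), hepatocyte markers (0.0759) and proliferation (0.0526), and in FFPE adenomas male-predominant (0.153) and fatty acid oxidation genes (0.056). Between FFPE adenomas and foci these were fatty acid oxidation (0.884, with the median turned) and male-predominant genes (0.187), inflammatory mediators (0.178) and periportal genes (0.112).

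The same-sign share of 78.17% was 83.13% in the matched fit, 78.2% with the frozen probe sets in both fixations and 75.58% without tumours 4 and 5 of animal 14.

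With 1 array or 1 animal left out in turn, the counts ranged from 0 to 81 for nodules, 570 (without animal 23) to 3651 for frozen adenomas, 469 (without animal 23) to 1861 for carcinomas and 734 (without animal 23) to 2520 for beta-catenin carcinomas. They ranged from 0 to 10 between the carcinoma groups (10 without beta-catenin carcinoma replicate 1), 0 to 214 for adenomas against nodules (214 without adenoma replicate 2) and 0 to 632 for carcinomas against adenomas (0 without carcinoma replicate 1 or 4 or adenoma replicate 6, 632 without surrounding replicate 2). In FFPE tissue they ranged from 202 (without animal 10) to 488 for foci, 109 (without animal 7) to 362 for adenomas and 0 to 2 for adenomas against foci. The same-sign share ranged from 74.4% to 81.1%.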

Other observations

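The C43 arrays, labelled both normal and surrounding tissue, entered no comparison, and their frozen pair (n = 2) had lower focus markers than any of the 7 surrounding arrays. Gstp1 was 9.84 and 9.72 against 10.30 to 13.47, Ggt1 was 6.70 and 7.04 against 8.17 to 9.29, and the NRF2 score was -1.51 in both against -1.19 to -0.15. The foci and oncofetal score was -1.25 and -1.26 against -0.98 to -0.24, the macrophage score -0.09 and -0.12 against 0.25 to 0.75, and the inflammatory score -0.35 and -0.27 against -0.12 to 0.20. Lower than in any surrounding array were also the scores of endothelial (-0.09 and -0.16, lowest other -0.04), lymphocyte (-0.12 and -0.13, lowest other -0.07) and blood cell markers (-0.38 and -0.41, lowest other -0.30), acute phase genes (0.13 and 0.07, lowest other 0.14) and glycolysis (-0.46 in both, lowest other -0.43). Cyp2c11 (13.49 and 13.45 against 11.76 to 13.53), Glul (10.60 and 10.45 against 9.91 to 10.80) and Mki67 (4.41 and 4.13 against 3.93 to 5.24) lay within the range of surrounding liver. The frozen pair correlated with the frozen surrounding arrays at 0.980 to 0.992 and the FFPE array with the FFPE ones at 0.875 to 0.943, and no test was run on 2 arrays.

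Surrounding liver itself varied between animals in Gstp1, with 13.47 in animal 11 and 10.30 and 10.48 in animal 23 (frozen), and with 12.17, 9.33, 7.15 and 8.86 in animals 10, 14, 18 and 7 (FFPE). The surrounding arrays of the carcinoma control sets had higher levels than the others of the acute phase opsonin Lbp by 2.44, of the protease inhibitor Mug1 by 2.63 and of the receptor Met by 1.89 (n = 3 and 4, adjusted p = 0.000139, 0.000101 and 0.000147). Zbtb41 was lower by 2.87 (adjusted p = 2.67e-05). These genes were chosen after their values were seen, as was the test between the batches.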
